A study of Homo sapiens with 6 samples.

How the data were processed

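The 6 samples were HepG2 cells, 3 given DMSO and 3 given 300 nM BFA for 24 h, with total RNA labelled with 1 dye, per the labels' protocols. Each sample was hybridised to 1 array. The deposited scanner tables were made with Agilent Feature Extraction version 10.7.3.1, named in both the file headers and the submitters' processing notes. They hold the processed signal of each spot as a linear intensity, background-subtracted and detrended within the array and not normalized between arrays, per the file headers. The median spot and local background intensities, and flags of other kinds (well above background, non-uniform, population outlier, saturated), are given beside it, per the file headers. The authors also deposited a table of log2 values per probe. Differences between arrays in that table had a correlation of 1 and a slope of 1 against differences of the log2 scanner signals, with a median offset of -0.08 to -0.10 for BFA arrays against DMSO replicate 1. This settles its log2 scale and its direction. Column medians were 0.01, -0.05 and -0.18 for DMSO and 0, -0.11 and 0.14 for BFA. What the probes were centred on and how arrays were scaled to each other stays unknown, and the table was used only as an alternative.

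The arrays carried 62976 spots, 58717 of them not controls, for 50599 probes. The design named in the file headers uses the genome build hg19. The files give accessions in place of gene symbols, and these were matched without version numbers to a table of RefSeq genes of the assembly GRCh38.p14. Because the builds differ, the table served for names only and coordinates are not given. Of the probes, 30275 had 1 symbol, 20324 had none and 0 had several, which gave 21743 genes. Of the probes without a symbol, 5034 were tested and 3857 passed; 1260 of these were at least 2-fold higher and 467 at least 2-fold lower.

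From the intensities, log2 of the processed signal minus each array's 75th percentile over all spots that are not controls was computed. Control spots were left out, and so were spots flagged as non-uniform or as population outliers (between 261 and 303 per array); 0 spots were saturated. Spots of a probe were averaged. A probe was tested if it was well above background on all 3 arrays of at least 1 group and measured on at least 2 arrays of each group, and each gene was represented by its brightest tested probe. This left 23613 probes (19975 passed, 12392 higher and 7583 lower) and 13932 genes. Several probes were tested for 3598 genes, and for 214 of the genes that passed, another probe passed in the opposite direction. Per array, 22799, 22916 and 23435 probes (DMSO) and 23433, 23877 and 23240 probes (BFA) were well above background. The 75th percentile of the processed signal was 332, 340 and 356 for DMSO and 288, 308 and 277 for BFA.

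The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, BFA minus DMSO, two-sided, no covariate), and p-values were adjusted by the Benjamini-Hochberg method over genes, and separately over probes. Genes were called at an adjusted p under 0.05, and 12254 genes had an unadjusted p under 0.05. Where a probe was not well above background on any array of a group, only a bound is given: the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal. Of the genes called, 406 in the higher and 377 in the lower direction have such a bound only. The list tests and list means nevertheless use the measured log2 fold changes of such genes, for example -6.93 for CYP8B1, whose bound is 36.2-fold lower. List means that include them are uncertain in size. The median SE of a log2 fold change was 0.05. The median SD between arrays was 0.06 in each group over genes. Over the 649 tested probes with at least 2 spots, the SD between spots on the same array was 0.06, and the SD between arrays of their averaged spots was 0.03 in each group.

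Gene lists were tested with camera (preset inter-gene correlation 0.01, two-sided, at least 5 tested members, adjusted over 35 lists), again with camera and an estimated correlation, and with fry, which asks whether a list's genes move on balance in a direction and does not compare them with other genes. The 36 lists hold 795 symbols, 1 of which was not found in the gene table. The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. By that rule the text names the 6 largest rises and 6 largest falls among genes that passed, were well above background on all 6 arrays and had groups that do not overlap; the 3 genes per direction with the highest bound; the 3 members of each list with the smallest adjusted p; and 26 genes chosen for their known part in secretion, ER stress, sterol regulation, hepatocyte function and growth. Identifier-type names were counted and not named, and some genes that the rule takes are not reported here. Other members are named where they are the exceptions in a list, after their values were seen.

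The procedure was tested on simulated data for the same comparison with 13932 genes, in which 200 genes were changed. It recovered 36% of genes changed 1.25-fold, 74% at 1.5-fold, 84% at 2-fold and 98% at 4-fold, and called 10 of 13709 unchanged genes. Of the 35 simulated lists, 1 was shifted by -1 on the log2 scale, and camera called that list and no other. The simulated noise was drawn independently for each probe and few genes were changed, whereas 87.6% of the genes passed in the data. The recovery rates and list calls of the simulation therefore need not hold for the data.

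The alternatives were normexp background correction (offset 50), quantile normalization, the median of the tested probes as the scale, no filter on dim probes, a filter requiring all 6 arrays, keeping spots with outlier marks, the mean of a gene's probes, an intensity trend with a robust prior, the authors' values, the replicate number as a block, and leaving out each array. Normexp was run on the median spot signal because the column of mean signals planned for it was not found in the tables. Scaling to 7 bright E1A spike-in controls (mean signal over 50) was added after seeing the data. Slide as a block could not be fitted, because each of the 2 slides holds 1 group. The figures were drawn with matplotlib 3.10.9 in Python 3.11.15.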

Results

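HepG2 is an established line of human liver cancer cells that keeps many hepatocyte functions, among them the secretion of plasma proteins. Brefeldin A (BFA) is a fungal metabolite that blocks the exchange factors of ARF GTPases, so that the COPI coat leaves the Golgi and Golgi membranes merge with the endoplasmic reticulum (ER). Total RNA was profiled from cells given 300 nM BFA or the solvent DMSO for 24 h, on 3 one-colour Agilent arrays per group. Each array held 62976 spots, and between 45.1% and 47.2% of the 50599 probes lay well above background. The number of arrays limits the precision. The 3 DMSO arrays were on slide 1 (scan 1) and the 3 BFA arrays on slide 2 (scan 2), so the design does not let slide and treatment be told apart. The labels do not say that the replicates were separate cultures, and p-values then measure only the spread between these samples, which may be technical. The single comparison that the design implies is which transcripts differed between BFA and DMSO.

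The transcripts of HepG2 cells differed widely between the treatments. Among the gene lists called by camera, ER chaperones, ER-associated degradation and the COPII and COPI coats were higher with BFA, and mitosis, DNA replication, secreted plasma proteins and hepatocyte transcription factors were lower. With an estimated correlation, 0 of the 20 calls remained (adjusted p = 0.0773 to 0.213 for these lists). Of 13932 genes tested with limma, 12199 (87.6%) passed an adjusted p of 0.05, 7179 higher and 5020 lower. At least 2-fold differences were found for 5835 genes, 3264 higher and 2571 lower. At least 8-fold differences were found for 403 genes in the higher and 446 in the lower direction. The groups did not overlap for 12452 genes (89.4%), where chance gives 10%. The median SD between arrays was 0.06 on the log2 scale in each group, and correlations across genes were 0.996 to 0.997 within and 0.867 to 0.87 between groups. The balance of directions depended on the scaling: 58.8% of calls and 55.9% of calls of at least 2-fold were higher here, against 48.3% and 42.8% when arrays were scaled to their spike-in controls, a setting chosen after seeing the data. The median log2 fold change of all genes was 0.23, and that scaling moved it by -0.27. Means of the lists called by camera are therefore also given relative to this median, and those of the other lists are not.

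Among genes well above background on all 6 arrays, the largest rise was that of BIRC7, an inhibitor of apoptosis, with a log2 fold change of 8.35 ± 0.03 (SE, n = 3 per group; adjusted p = 3.04e-08), 325-fold. KLHDC7B followed with 287-fold, MEI1, a gene of meiosis, with 255-fold, and PDCD1, an inhibitory receptor of T cells, with 223-fold. HCST, a signalling adaptor of immune cells, was 165-fold higher and APOA4, an apolipoprotein, 158-fold. The mean normalized log2 signals of these genes on DMSO arrays were, in that order, -2.90, -3.77, -2.17, -1.71, -1.2 and -0.03. Most of these folds thus rest on low signals with DMSO, and the SE measures only the spread between arrays. The largest falls were those of SLC13A3, a dicarboxylate transporter, at -7.52 ± 0.09 (184-fold lower; adjusted p = 9.24e-08), and of SERPINA7, the thyroxine-binding globulin, 159-fold lower. HPR was 114-fold, SPP1 (osteopontin) 111-fold, HP (haptoglobin) 92.9-fold and FABP1, the liver fatty acid binding protein, 59.1-fold lower. The mean signals of the genes with the largest falls on BFA arrays were, in that order, -3.48, -3.56, -0.79, -1.2, 0.98 and 1.89. HP and HPR are near-identical copies, and their probes may share signal, so the share of each is uncertain. LCN2, a secreted lipocalin, was not well above background on any DMSO array and was at least 391-fold higher with BFA (adjusted p = 5.5e-08). PRPH2 was at least 104-fold and KIF1A, a neuronal kinesin, at least 97.1-fold higher by the same measure. In the other direction, NFE2 was at least 90.2-fold, FAM151A at least 64.8-fold and DIO1, a deiodinase of thyroid hormone, at least 53.7-fold lower, none of them well above background on any BFA array. In the higher direction, 1 identifier-type name was passed over in each ranking.

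All 21 tested genes for ER chaperones and folding enzymes rose, with a mean log2 fold change of 1.93, or 1.69 relative to the median of all genes (camera, adjusted p = 2.12e-05; adjusted p = 0.0773 with an estimated correlation). HSPA5, the ER chaperone BiP, rose by 4.61 ± 0.04 (SE, n = 3 per group), 24.4-fold, from a normalized log2 signal of 2.01 ± 0.04 (SD) to 6.62 ± 0.04. DNAJB9, a co-chaperone of HSPA5, rose 10.1-fold and MANF 6.28-fold. In the list of ER-associated degradation, which returns misfolded proteins to the cytosol, 19 of 20 genes rose, HERPUD1 8.86-fold, ERLEC1 6.44-fold and the ubiquitin ligase gene SYVN1 5-fold (mean 1.56, 1.33 relative to the median; adjusted p = 0.000161, and adjusted p = 0.0773 with an estimated correlation). Of 27 genes for the ER translocon and N-glycan transfer, 26 rose, among them SRP54 at 7.63-fold, SEC61A1 at 3.81-fold and SSR4 at 3.06-fold, and STT3B fell by 0.22 (mean 1.14, 0.90 relative to the median; adjusted p = 4.29e-05, and adjusted p = 0.0916 with an estimated correlation).

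**Figure D1:**
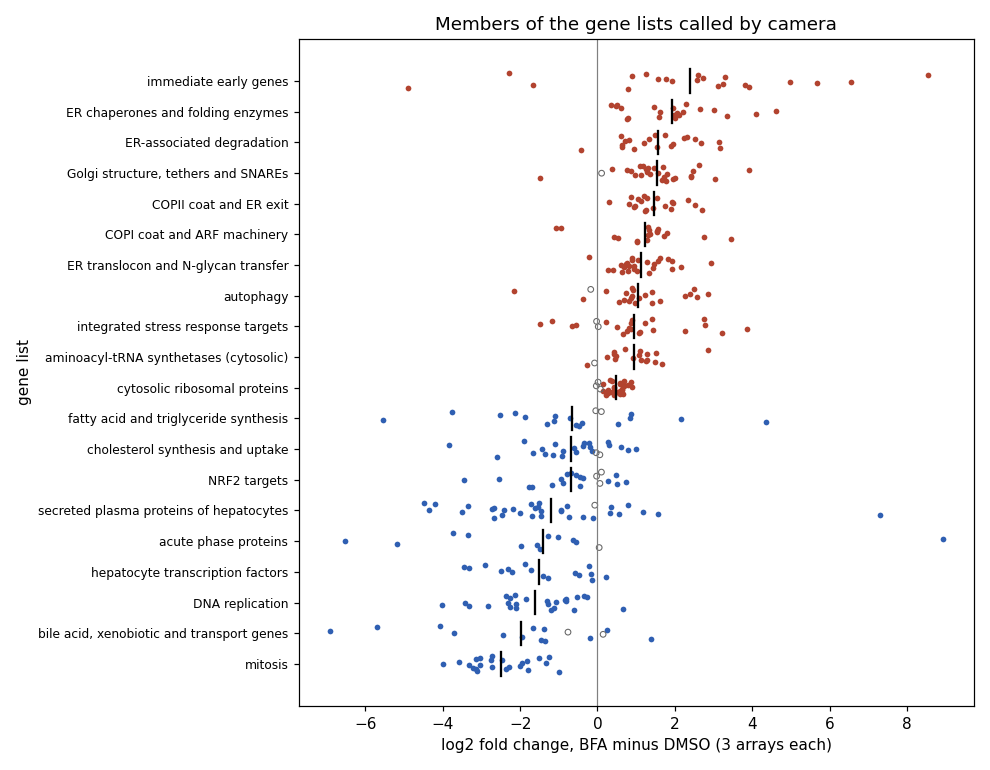
Log2 fold change (BFA minus DMSO, horizontal axis, 3 arrays per group) of each tested member of the 20 gene lists called by camera (vertical axis). Filled points passed an adjusted p of 0.05 (red for a list called higher, blue for a list called lower), and open points did not. Black bars mark list means, which run from -2.50 for mitosis to 2.40 for immediate early genes. Genes with a bound only are drawn at their measured value. No call remained with an estimated correlation.

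All 20 tested genes of the COPII coat and ER exit rose (mean 1.46, 1.22 relative to the median; adjusted p = 4.29e-05, and adjusted p = 0.0773 with an estimated correlation), with MCFD2 at 6.54-fold, SEC24D at 5.09-fold and SEC24A at 3.79-fold. In the list of COPI coat and ARF machinery, which holds the targets of BFA, 16 of 18 genes rose and COPG2 and COPZ1 fell by 1.08 and 0.94 (mean 1.22, 0.99 relative to the median; adjusted p = 0.00194, and adjusted p = 0.0956 with an estimated correlation). ARF4 rose 10.9-fold (3.44 ± 0.04 SE), ARFGAP1 6.74-fold and COPA 3.48-fold, whereas ARF1 rose 2.03-fold and GBF1, the exchange factor at the early Golgi, 2.46-fold. Of 28 genes for Golgi structure, tethers and SNAREs, 26 rose, KDELR3, a retrieval receptor, 15.1-fold, COG6 8.25-fold and YKT6 6.16-fold (mean 1.53, 1.29 relative to the median; adjusted p = 2.5e-05, and adjusted p = 0.0773 with an estimated correlation). GIPC1 in that list was 2.82-fold lower, and GORASP1 did not pass (0.11). The list of Golgi glycosylation enzymes was not called (mean -0.23, adjusted p = 0.243): 9 members rose, FUT1 4.38-fold, and 14 fell, MGAT5 9-fold and GALNT1 3.35-fold.

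Several genes for stress-related transcription factors were higher with BFA. CREB3, which is cut in the Golgi to become active, rose 19.1-fold, ATF6 6.87-fold, CREB3L1 2.18-fold and ATF4 2.12-fold. CREB3L2 and the hepatic CREB3L3 fell by 0.40 and 1.28, and XBP1 fell by 0.83 from a high level. TFE3 differed by 0.22 ± 0.06 (SE, adjusted p = 0.0139), a value that was -0.0452 with spike-in scaling. Among targets of the integrated stress response, 18 of 24 rose and 4 fell (mean 0.95, 0.72 relative to the median; adjusted p = 0.0258, and adjusted p = 0.381 with an estimated correlation). DDIT3, the transcription factor CHOP, rose 14.6-fold, ATF3 9.26-fold, PPP1R15A 6.85-fold, TRIB3 2.64-fold, GDF15 1.77-fold and ASNS 1.59-fold. The 4 that fell were PSAT1, PHGDH and PSPH, the enzymes of serine synthesis, and the amino acid transporter gene SLC7A5. Of 19 genes for cytosolic aminoacyl-tRNA synthetases, 17 rose, WARS1 7.31-fold, EPRS1 2.83-fold and RARS1 2.42-fold (mean 0.95, 0.71 relative to the median; adjusted p = 0.0024, and adjusted p = 0.266 with an estimated correlation).

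Immediate early genes, which respond within minutes to many stimuli, rose for 18 of 21 members (mean 2.40, 2.16 relative to the median; adjusted p = 0.00286, and adjusted p = 0.23 with an estimated correlation). FOS was 31.4-fold and DUSP1 15-fold higher, and KLF2, well above background on 2 of the 3 DMSO arrays, 372-fold, while MYC, DUSP6 and CCN2 fell by 2.29, 1.67 and 4.89. Of 23 autophagy genes, 20 rose, MAP1LC3B 7.29-fold, BNIP3L 5.9-fold and WIPI1 5.65-fold, and TFEB and ATG7 fell by 2.16 and 0.37 (mean 1.05, 0.82 relative to the median; adjusted p = 0.0024, and adjusted p = 0.0956 with an estimated correlation). Genes for cytosolic ribosomal proteins showed small differences, with 27 of 30 higher, among them RPLP2 at 1.87-fold and RPL18 at 1.57-fold (mean 0.47, 0.24 relative to the median; adjusted p = 0.000685, adjusted p = 0.459 with an estimated correlation). That list was not called after quantile normalization (adjusted p = 0.621), and many ribosomal protein genes have near-identical pseudogenes that could share signal.

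All 23 tested mitosis genes fell (mean -2.50, -2.74 relative to the median; adjusted p = 2.06e-09, and adjusted p = 0.109 with an estimated correlation). KIF20A was 12-fold, CENPE 8.19-fold and NDC80 5.51-fold lower, and the proliferation marker MKI67 fell by 2.74 ± 0.09 (SE). Of 25 DNA replication genes, 24 fell, MCM5 by 3.42 on the log2 scale, GINS1 10-fold and TYMS 4.39-fold, and the licensing factor gene CDC6 rose by 0.66 (mean -1.62, -1.85 relative to the median; adjusted p = 2.88e-07, and adjusted p = 0.213 with an estimated correlation). CDKN1A, an inhibitor of cyclin-dependent kinases, rose 3.73-fold. The p53 target list that contains it was not called (mean -0.31, adjusted p = 0.0684): 6 members rose and 12 fell, DDB2 6.4-fold, FDXR 2.98-fold and PHLDA3 2.69-fold.

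**Figure D2:**
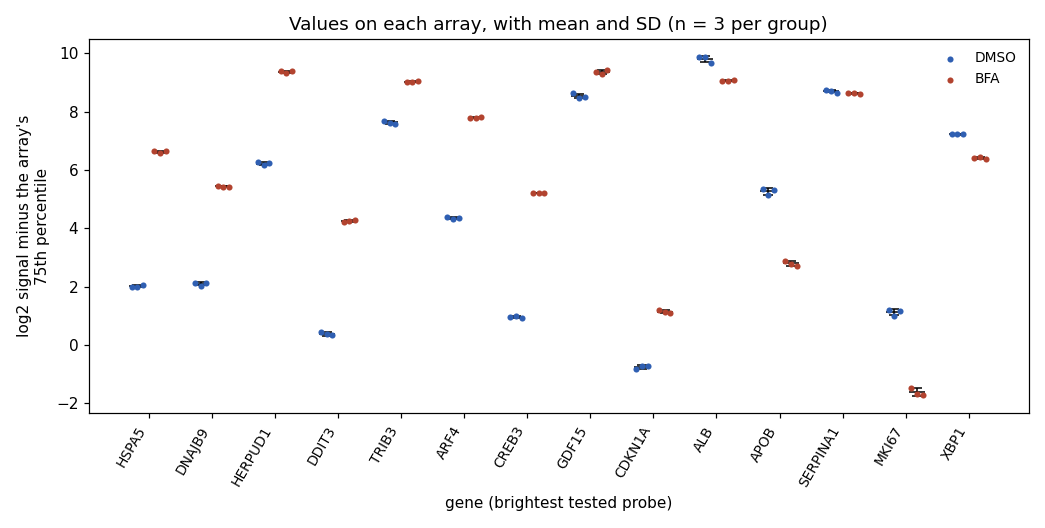
Normalized log2 signal (log2 of the processed signal minus the array's 75th percentile, vertical axis) of part of the genes fixed in advance (horizontal axis) on each of 3 DMSO (blue) and 3 BFA (red) arrays, with the mean and SD in black. Signals of HSPA5 moved from 2.01 to 6.62 and those of APOB from 5.27 to 2.80, while SERPINA1 had means of 8.70 and 8.63.

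Of 33 tested genes for plasma proteins that hepatocytes secrete, 25 fell and 7 rose (mean -1.21, -1.45 relative to the median; adjusted p = 5.16e-05, and adjusted p = 0.198 with an estimated correlation). TTR (transthyretin) was 22.5-fold and APOH 11.3-fold lower, APOB fell by 2.48 ± 0.07 (SE, n = 3 per group), and ALB (albumin) fell by 0.74 ± 0.06. The 7 that rose were the apolipoprotein genes APOA4, APOC1, APOC2, APOE and APOM, with SERPINC1 and ITIH3. SERPINA1 (alpha-1 antitrypsin) did not pass (-0.07 ± 0.04, adjusted p = 0.111), but passed as lower in 6 other settings, with values down to -0.47 after quantile normalization. Among acute phase proteins, 11 of 13 fell, SERPINA3 13.4-fold, and LCN2 rose (mean -1.41, -1.64 relative to the median; adjusted p = 0.000685, and adjusted p = 0.0916 with an estimated correlation). Of 16 genes for hepatocyte transcription factors, 15 fell, PROX1 7.54-fold, NR0B2 5.67-fold and RXRA 3.66-fold, and ESRRA rose by 0.22 (mean -1.52, -1.76 relative to the median; adjusted p = 0.00012, and adjusted p = 0.0773 with an estimated correlation). Genes for bile acid synthesis, xenobiotic metabolism and transport fell for 11 of 15 members (mean -1.99, -2.22 relative to the median; adjusted p = 0.00194, and adjusted p = 0.0956 with an estimated correlation). SULT2A1 was 51.6-fold and CYP27A1 5.4-fold lower, and CYP8B1, not well above background on any BFA array, at least 36.2-fold lower.

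Lipid genes moved in both directions. Of 24 genes for cholesterol synthesis and uptake, 17 fell, ACAT2 6.03-fold and TM7SF2 3.71-fold, and 5 rose (mean -0.68, -0.91 relative to the median; adjusted p = 0.00355, and adjusted p = 0.0956 with an estimated correlation). The probe for INSIG1 was not well above background on any array. In fatty acid and triglyceride synthesis, 12 of 19 genes fell, GPAM 5.72-fold, and 5 rose, AGPAT2 20.6-fold and ELOVL5 4.46-fold (mean -0.67, -0.90 relative to the median; adjusted p = 0.0376, and adjusted p = 0.167 with an estimated correlation). That call also ended with quantile normalization (adjusted p = 0.0528), the mean of a gene's probes (0.071), the authors' values (0.0916) and spike-in scaling (0.0608). NRF2 targets, genes of the response to oxidants, fell for 13 of 20 members, HMOX1 10.9-fold, NQO1 5.81-fold and AKR1B10 3.4-fold (mean -0.68, -0.91 relative to the median; adjusted p = 0.00913, and adjusted p = 0.123 with an estimated correlation). In that list GCLC, FTH1, SRXN1 and GCLM rose by 0.74, 0.51, 0.49 and 0.26, and the remaining tested members did not pass.

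The remaining lists were not called by camera. Extracellular matrix and integrin genes came nearest (mean -0.49, adjusted p = 0.0516), a result that depended on the setting (0.0165 to 0.135, under 0.05 in camera in 5 alternatives, among them those without BFA replicate 1, 0.0479, or 3, 0.0439), with TIMP1 29.3-fold higher and LAMB1 and COL18A1 8.89-fold and 7.53-fold lower. For targets of NF-kappaB the adjusted p was 0.0976 (CCL20 12.9-fold lower, NFKB2 4.98-fold and IER3 2.95-fold higher), and for the interferon response 0.13 (ISG15 13.2-fold higher, IFIT1 5.4-fold lower, and IFIT3, not well above background with BFA, at least 6.38-fold lower; 5 of 15 members rose and 10 fell, mean -0.50). Adjusted p was 0.175 for fatty acid oxidation (ACADS 4.79-fold, ACAA1 3.72-fold and HADH 2.99-fold lower), 0.26 for nuclear-encoded oxidative phosphorylation (NDUFS1 3.06-fold and SDHB 2.23-fold higher, ATP5F1C 1.93-fold lower) and 0.687 for glycolysis and hypoxia (ANKRD37 4.92-fold and PFKFB4 4.19-fold higher, SLC2A1 3.33-fold lower). It was 0.315 for cytosolic heat shock proteins (HSPH1 2.94-fold and BAG3 2.3-fold higher, HSPB1 1.99-fold lower) and 0.621 for lysosomal proteins (GUSB 2.9-fold and NPC2 2.56-fold lower). For ribosome biogenesis it was 0.69 (RRP12 15.8-fold and NOLC1 2.7-fold higher, UTP20 2.93-fold lower), and for cell death receptors and the BCL2 family 0.9 (BMF 8.4-fold lower, HRK 6.5-fold higher). The means of these last lists, 0.15 and 0.01, lay above 0 while the test, which compares a list with the other genes, pointed down. For lysosomal proteins the mean was -0.02 and the median 0.03.

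Of the 4 lists of markers of other cell types, camera called none of the 3 it tested, while fry, which does not compare a list with other genes, called cholangiocyte (lower, adjusted p = 5.16e-07), endothelial (higher, 0.041) and leukocyte markers (lower, 1.88e-05). Cholangiocyte and progenitor markers had an adjusted p of 0.29 in camera, with KRT23 4.5-fold lower and CD24 2.65-fold higher. Endothelial markers had an adjusted p of 0.69: TIE1 was at least 7.31-fold higher, CDH5 1.57-fold higher, a call lost with quantile and spike-in scaling, and PECAM1, well above background on 1 of 3 BFA arrays, 12.8-fold lower. For leukocyte markers it was 0.626 (CD14 7.19-fold lower, CD68 1.84-fold higher; mean -0.10, median 0.00). Of the fibroblast and stellate markers 4 were tested, too few for the list test, and 3 fell and DES rose by 0.53: ACTA2 was 6.27-fold, TAGLN 4.63-fold and PDGFRB at least 3.4-fold lower.

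Camera called 20 of the 35 tested lists with its preset correlation, 11 higher and 9 lower, and 0 with an estimated correlation, while fry called 35, in the opposite direction to camera for the interferon response, ribosome biogenesis and cell death lists. Camera compares a list with the other genes of the same comparison, so its p-values say little about the spread between arrays. In each of the 35 lists, the numbers of members that rose and fell were the same when adjusted over the list alone.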

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

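Across the alternatives chosen in advance, 11009 to 12491 genes changed and 4099 to 6405 genes changed at least 2-fold, each within 1.5 times the count reported. Leaving out each array gave 11877 to 12009 and 5801 to 5881. Of the genes called both ways, 95 differed in direction with quantile normalization, 104 with the authors' values, 74 with the mean of a gene's probes and 71 with spike-in scaling, the alternative added after seeing the data (11746 genes, 5578 at least 2-fold). The replicate numbers did not pair the samples: the deviations of same-numbered arrays correlated at 0.03, 0.01 and -0.04, and only replicate 1 correlated best with its own number in the other group. With the replicate number as a block, 11889 genes changed and 5822 changed at least 2-fold, and no list call changed. Slide as a block was not run, since each slide holds 1 group. Signal over background limits the dim genes, of which only bounds can be given. Except where a construction is named, the cause of a lost or gained call was not tested.

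With a correlation between genes estimated from the arrays in place of the preset 0.01, the 20 calls of gene lists ended. Among them the estimate ran from -0.043 for cholesterol genes to 0.530 for ribosomal proteins. It lay below the preset for some lists, such as ER chaperones (0.003) and Golgi structure (-0.020). For others, such as mitosis (0.208), it lay above. With an estimate, camera also takes its p-values from a wider distribution set by the number of arrays, which the preset form does not. The effects of the estimate and of that distribution were not separated. An ended call therefore does not show that members moved together between arrays. The adjusted p was 0.0773 for ER chaperones, ER-associated degradation, COPII, Golgi structure and hepatocyte transcription factors, 0.0916 for the ER translocon and acute phase proteins, and 0.0956 for COPI, cholesterol, bile acid genes and autophagy. It was 0.109 for mitosis, 0.123 for NRF2 targets, 0.167 for fatty acid synthesis, 0.198 for plasma proteins, 0.213 for DNA replication, 0.23 for immediate early genes, 0.266 for aminoacyl-tRNA synthetases, 0.381 for the integrated stress response and 0.459 for ribosomal proteins. Without a filter on dim probes, 5 lists were called with an estimated correlation.

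Fry, which does not compare a list with other genes, also called the 15 lists that camera did not: Golgi glycosylation (adjusted p = 0.000776), fatty acid oxidation (7.71e-07), p53 targets (3.7e-06), cell death (1.46e-05), heat shock proteins (3.49e-06), NF-kappaB targets (1.92e-06), interferon response (0.000665), lysosomal proteins (0.000204), ribosome biogenesis (1.87e-05), oxidative phosphorylation (7.66e-06), glycolysis (0.000683), extracellular matrix (1.35e-07), cholangiocyte markers (5.16e-07), endothelial markers (0.041) and leukocyte markers (1.88e-05). For the interferon response, ribosome biogenesis and cell death it pointed up, where camera pointed down; of the interferon genes 10 of 15 were lower, with a mean of -0.50.

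Quantile normalization ended the call of ribosomal proteins (adjusted p = 0.621; 6.46e-05 to 0.0185 in the other settings of camera with its preset correlation). The call of fatty acid and triglyceride synthesis ended with quantile normalization (0.0528), the mean of a gene's probes (0.071), the authors' values (0.0916) and spike-in scaling (0.0608), and its lowest value was 0.0101. Extracellular matrix genes were called with normexp (0.0311), no filter (0.0265) and the filter on all 6 arrays (0.0165), and leaving out each array gave 0.0439 to 0.062, under 0.05 without BFA replicate 1 (0.0479) or 3 (0.0439); the highest value was 0.135. The p53 targets were called with no filter (0.019), with a highest value of 0.0921. Among named genes, TFE3 turned to -0.0452 with spike-in scaling and lost its call with quantile and median scaling, CDH5 lost its call with quantile and spike-in scaling, and SERPINA1 passed in 6 settings, lower in each (-0.07 to -0.47).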

Other observations

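The tests of gene families, spike-ins, splits of the arrays, markers, scaling and early genes given here were chosen after the results were seen. The test of other probes was written before its result was seen.

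Gene families, grouped by the letters that open their symbols, were tested as well, and some of their members are in the fixed lists: GOLGA in the Golgi list, ATG in autophagy, AKR in NRF2 targets, DNAJC in ER chaperones and CYP in the bile acid and cholesterol lists. Of 163 families with at least 10 tested genes, camera called 10 higher and 6 lower, and 0 with an estimated correlation. Aldo-keto reductase genes (AKR), which reduce aldehydes and steroids, fell for 11 of 13 members (mean log2 fold change -0.77; adjusted p = 0.0134, and adjusted p = 0.74 with an estimated correlation). Co-chaperone genes of the DNAJC family rose for 22 of 27 (mean 0.97; adjusted p = 0.0257, and adjusted p = 0.74 with an estimated correlation). These calls, and those of GOLGA (20 of 20 higher, adjusted p = 0.0169) and ATG (16 of 17 higher, 0.021), held under quantile, median and spike-in scaling and with the authors' values; for both, adjusted p = 0.74 with an estimated correlation. Translation initiation factors (EIF, 40 of 51 higher, adjusted p = 0.0134) and the proteasome family PSMD (14 of 15 higher, 0.0327) were not called after quantile normalization (0.124 and 0.0923) or spike-in scaling (0.0722 for each), PSMD was not called with the authors' values (0.0508), and neither was called with an estimated correlation (adjusted p = 0.74 for each). Cytochrome P450 genes (CYP) fell for 17 of 27 (mean -1.06; adjusted p = 0.0327, adjusted p = 0.74 with an estimated correlation), a call also lost with quantile (0.0639) and spike-in scaling (0.0722) and the authors' values (0.0887).

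By transcript class, 121 of 200 small nucleolar RNA genes were higher and 29 lower (median log2 fold change 0.45). Of 327 transcribed pseudogenes, 200 were higher and 67 lower (median 0.48), and of 780 long non-coding RNA genes, 408 were higher and 207 lower (median 0.36). Of 12574 protein-coding genes, 6423 were higher and 4709 lower (median 0.21). With spike-in scaling the medians were 0.18, 0.21, 0.09 and -0.05 in that order, and the counts of higher and lower genes were 80 and 45, 157 and 92, 336 and 259, and 5084 and 5661. The differences between classes were not tested; as symbol families, the small nucleolar SNORD and SNORA genes were not called by camera (adjusted p = 0.27 and 0.411), and their means of 0.45 and 0.36 were 0.18 and 0.10 with spike-in scaling.

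Most genes differed between the groups, which also lay on different slides. The 7 bright spike-ins (mean signal over 50, chosen after seeing the data) are a kind of control normally added to RNA before labelling. Their differences between the slides spanned 0.156 on the log2 scale. For genes this bright in both groups, that span argues against labelling, hybridisation or scanning as the whole cause of changes of at least 2-fold. Over all genes called at least 2-fold, the median absolute log2 fold change was 1.69. The dimmer spike-ins differed by -0.05, -0.11 and -0.41 between the slides. Changes of genes dimmer than the bright spike-ins in either group are therefore not decided. For the 6364 smaller changes, with a median of 0.541, the spike-ins do not decide, and slide and treatment cannot be told apart; the spike-ins do not test steps before labelling, and the labels name no batch of those. The 10 splits of the arrays into 3 and 3 are too few for a share under 0.05: the real split gave 12199 genes and 5835 at least 2-fold in limma and was the only 1 as large, and the highest of the others was 0 for each, with 12 to 27 genes at an unadjusted p under 0.05. Every other split mixes both treatments within a group, so the treatment difference enters the spread that limma reads and low counts follow. The count of 0 is therefore not a rate of false calls. For gene lists, 3 of the 10 splits gave as many as the real 20, with 20 as the highest other, and each other split still sets 2 arrays of a treatment against 1, so that part of the treatment difference remains in the gene statistics that camera reads.

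The 403 genes that rose at least 8-fold include genes known from other cell types, such as PDCD1 and HCST of lymphocytes and KRT17 and KRT14 of epidermis (KRT17 and KRT14 were chosen after their values were seen). T or NK cells may be a source, and of 10 tested T and NK cell markers 7 were higher (CD3D by 1.77, adjusted p = 0.00272) and 2 lower. Of the 20 markers on the array, 45% were not above background on any BFA array, CD3E, IL7R, NKG7 and CCL5 among them. IL2RB and CD2 were called higher and were above background on all 3 BFA arrays and 0 DMSO arrays, so the sizes of their rises are not given. These markers were singled out after their values were seen, so the test does not decide whether such cells were present. In addition, 2 earlier forms of this test were set aside after their results were seen. In the first, PTPRC was above background on all 3 arrays of each group and differed by -0.10 (adjusted p = 0.72), which decided nothing. In the other, 35% of the 20 markers were called higher, a share that counts untested markers as not rising. Epidermal cells are not decided on either, for the same reason. Of their tested markers, 8 of 9 were higher and 1 lower, but 52.6% of the 19 on the array, with KRT5, KRT6A and KRT1, were not above background on any BFA array. KRT16 was above it on all 3 BFA arrays and 0 DMSO arrays. An earlier form gave 42.1% called higher, counted in the same way. On all 3 DMSO arrays, 7 of the T and NK cell markers and 6 of the epidermal markers were above background. Single faulty or cross-hybridising probes stay open: of 149 other probes of these genes, 74.5% were higher and 0 lower, against 26% of all probes being higher, just short of the 75% set beforehand. Only 99 of the genes have such probes, and a response to the treatment also stays open, as untested.

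Mitosis and DNA replication genes fell together. Scaling between arrays is argued against as the cause, since the mean log2 fold change of either list was at most -1.62 under the 5 scalings compared, the authors' values among them. A general loss of short-lived transcripts could lower such genes and stays open: 14.3% of immediate early genes, whose transcripts are short-lived, were lower and 18 of 21 higher, but stimuli induce these genes, so they do not decide what happened to short-lived transcripts that were not induced. An effect of the treatment stays open, as untested.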
